A study of Mus musculus with 6 samples.

How the data were processed

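Polyadenylated RNA of mouse early 2-cell embryos was amplified by Smart-seq2, which primes reverse transcription with oligo-dT and amplifies full-length cDNA by PCR, and sequenced as paired reads, per the labels' protocols. The protocol does not mark strand, so antisense and overlapping genes cannot be told apart. Reads were processed with cutadapt 1.16 and STAR on mm10, per the submitters' processing notes; the version of STAR and the program that counted reads are not given in the sources used here. The deposited tables hold 1 file per library with 55549 rows, of which 55335 have an Ensembl gene ID with a symbol, per the file headers. GENCODE M21, on the same assembly, holds 55154 of these IDs and gave positions, biotypes and exon lengths.

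The deposited expected count is the authors' estimate of fragments per gene, which shares ambiguous fragments between genes and need not be whole. Between 10.6% and 16% of rows were not whole numbers, within a tolerance of 0.005, and expected counts were rounded before testing. The deposited TPM values are scaled by the authors for length and depth and were used only to look at the tables. Totals per library were 11173295 to 14737152.

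EtP was compared with control (3 libraries each) by edgeR 4.0.16 in R 4.3.3, with filterByExpr at its defaults, TMM scaling, robust quasi-likelihood fits, group as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM uses TMM-scaled library sizes, and values are mean ± SD. TMM factors were 1.198 to 1.385 in control and 0.738 to 0.833 in EtP, which reflects different RNA composition. PCR copies were not marked by molecular identifiers. Library measures were compared with exact two-sided permutation tests. A count of 0 was taken to allow 3 counts over the group.

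The tests, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, fry and camera on voom values as alternatives. Named genes were the 12 largest increases and 12 largest decreases among called genes with a symbol that is not a predicted locus, a mean of at least 10 CPM and no overlap between groups (10% of genes meet this last condition by chance), and per list up to 4 members with the smallest p and a mean of at least 5 CPM, or for other cell types the 2 with the highest mean. Some genes that the rule selects are not reported here. Other genes named were chosen after their values were seen. Alternatives were RLE, upper-quartile and library-size scaling, other filters and thresholds, DESeq2 1.42.0, limma-voom, a replicate block, removal of mitochondrially encoded genes and leaving out each library. Removal of ribosomal RNA rows and of rows without an Ensembl ID was added after seeing the data. Figures were drawn with matplotlib 3.10.9.

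The edgeR step was tested on simulated counts for this comparison, with 13843 genes tested. Of 98 genes changed 4-fold 83.7% were called and of 97 changed 2-fold 20.6%, each called gene in the right direction; 8.1% of calls were unchanged genes. Changes of 2-fold or less can thus be missed. The simulation changed far fewer genes than were called in the data, as many upward as downward. Its shares may therefore differ from those of the real comparison, and it did not test the scaling.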

Results

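In mouse embryos the embryonic genome takes over from RNA stored in the egg in the course of the 2-cell stage. RNA sequencing was carried out on embryos at the early 2-cell stage. One group was control embryos and the other had been placed at 4 h after fertilization in culture medium with 40 uM ethylparaben (EtP), an ester of 4-hydroxybenzoic acid used as a preservative. The series states that most exposed embryos stopped at this stage, and the comparison asks how their transcripts differed from those of controls. There were 3 libraries per group. The labels give neither the number of embryos per library nor whether the libraries of a group came from separate cultures. The p-values thus measure the spread between these libraries, which may be technical. Nor do the labels give the hour at which control and EtP embryos were collected, so the groups may differ in age. Library totals ranged from 11173295 to 14737152 estimated counts. Correlations of log2 CPM, counts scaled for library size, were 0.931 to 0.98 within groups and 0.87 to 0.905 between groups, and no pair of libraries agreed within sampling noise.

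Fewer genes were detected in EtP embryos. At least 1 count was found for 26089 ± 79.4 genes in control and 19577 ± 215 in EtP libraries (mean ± SD, n = 3 each). The 50 most abundant genes took 27.9% ± 2.04 of counts in control and 35.9% ± 1.89 in EtP, and the protein-coding mitochondrial genes took 3.01% ± 0.901 and 1.15% ± 0.162 (SD, n = 3). For each of these measures the groups did not overlap, with an exact two-sided permutation p of 0.1 and an adjusted p of 0.13 over 8 measures. The smallest p that 3 against 3 allows is 0.1. Total counts did not separate the groups (exact permutation p = 0.8).

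Between EtP and control embryos, 1797 of 14373 tested genes were higher and 2601 lower in EtP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Large changes were mostly decreases. Of the called genes, 24 were at least 8-fold higher and 770 at least 8-fold lower. Of the 770, 426 were protein-coding, 184 other RNA genes and 146 pseudogenes, where 11780, 1667 and 775 genes of these classes were tested. Of the 24, 14 were protein-coding, 5 other RNA genes and 5 pseudogenes. Among protein-coding genes 1438 were higher and 1841 lower, and among pseudogenes 115 were higher and 224 lower. The numbers depend on how libraries are scaled, because RNA composition differed between groups. With library size alone the median of all genes moved by -0.73 on the log2 scale, and 545 genes were higher and 7618 lower, so that 93.3% of calls were decreases against 59.1% in the main fit. Directions below are relative to the main scaling.

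**Figure D1:**
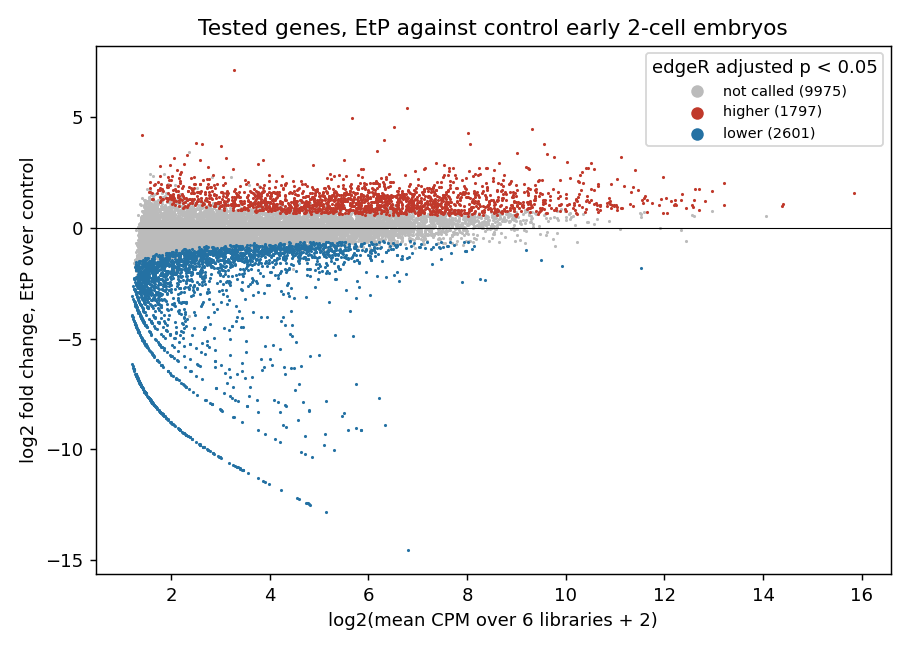
Each point is a tested gene, with log2 of the mean CPM over 6 libraries plus 2 on the horizontal axis and the fitted log2 fold change of EtP over control on the vertical axis. The 1797 genes called higher are red and the 2601 called lower are blue. Curved rows of points at the lower left are genes with few or no EtP counts, whose fitted folds depend on the prior count.

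Dnmt1, the maintenance DNA methyltransferase, was at 99.2 ± 2.34 CPM in control and 1399 ± 155 CPM in EtP (SD, n = 3), a log2 fold change of 3.82 ± 0.22 (SE; edgeR adjusted p = 2.52e-06). It lies on chromosome 9 from 20907209 to 20959888 of mm10. Txnip, which binds thioredoxin, rose from 54.6 ± 8.83 to 1214 ± 106 CPM, and Tsc22d1, a transcriptional regulator, from 140 ± 10.9 to 1433 ± 72.6 CPM. The nucleolar factors Gnl2 and Lyar and the terminal transferase partner Dnttip2 rose by 4.00 ± 0.26, 3.48 ± 0.22 and 3.81 ± 0.26 on the log2 scale. Ssb, the La protein that binds new RNA polymerase III transcripts, rose from 440 ± 220 to 4036 ± 654 CPM. The homeobox gene Cphx2, the splicing factor Zcrb1, the proteasome subunit Psma7 and the Mediator subunit Med20 rose by 4.97 ± 0.69, 4.31 ± 0.35, 3.19 ± 0.31 and 3.07 ± 0.30. Srp54b was higher by 4.56 ± 1.02, but its control libraries ranged widely (7.28 ± 7.45 CPM), its call was lost without control replicate 1 or 2 (edgeR adjusted p = 0.0625 and 0.0691), and its reads may be split with a near-identical copy.

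The 12 largest decreases among genes selected by the naming rule were mostly genes of the 2-cell-transient programme. BB287469 on chromosome 12 had 25.1 ± 5.34 CPM in control and no count in any EtP library, at least 267-fold lower against a floor of 3 counts over the group. Zscan4e had 1597 counts in control and 1 in EtP, 986-fold lower with a counting interval of 177 to 39000. For Usp17la the ratio was 713-fold (128 to 28200), for Zscan4a 553-fold (153 to 4570), for AF067061 362-fold (100 to 2990) and for Usp17lb 233-fold (79.7 to 1130). These intervals are 95% exact binomial intervals and, like floors, cover counting error only. Zfp352, a zinc-finger gene on chromosome 4, fell by 8.50 ± 0.36 on the log2 scale, from 83.8 ± 15.9 to 0.221 ± 0.0277 CPM (edgeR adjusted p = 7.04e-07). Pramef25, D13Ertd608e, AF067063 and Zscan4f fell, with log2 fold changes of -7.87, -6.26, -5.91 and -5.75, and Usp17lc fell from 24.7 ± 4.76 to 0.276 ± 0.146 CPM. Many of these genes have near-identical copies, so values of single copies are uncertain.

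**Figure D2:**
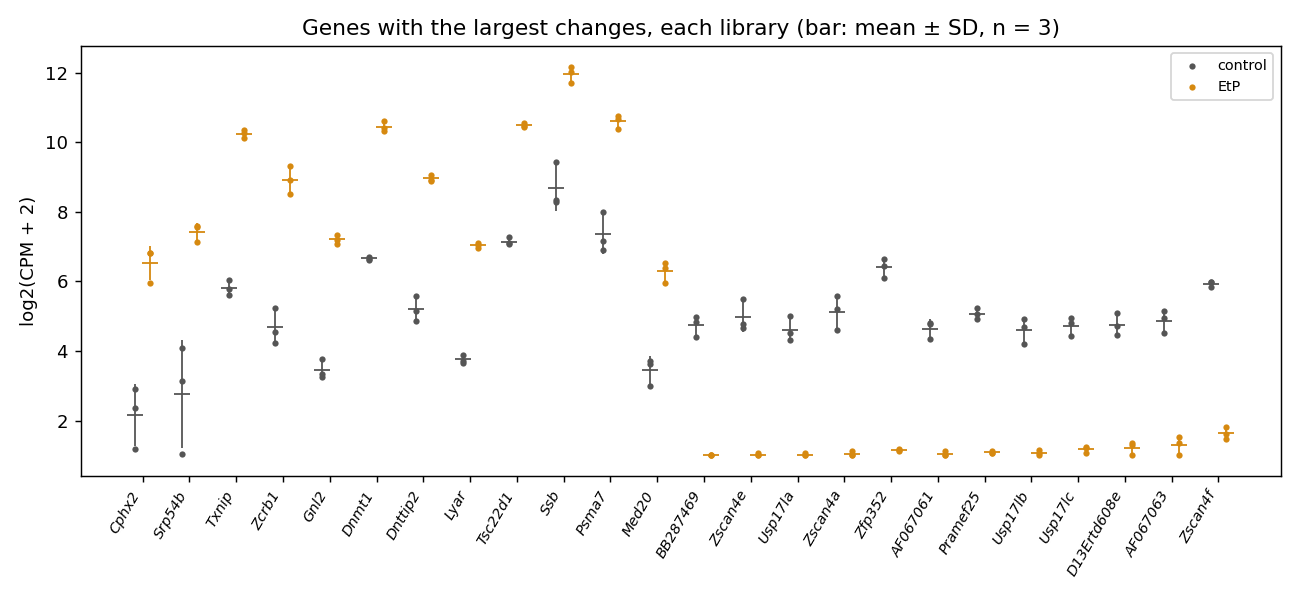
Points give log2 of CPM plus 2 in each library for the 12 genes with the largest increases and the 12 with the largest decreases, with bars for the mean ± SD (n = 3). In each of the 24 genes the 3 EtP libraries lie on one side of the 3 control libraries, which was a condition of the rule.

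Genes known to be expressed briefly at the 2-cell stage were lower in EtP as a group. Of 40 tested members 37 were lower and 1, D5Ertd577e, was higher (38 and 2 adjusted over the list alone), with a median log2 fold change of -6.96. With the 9 members that had no EtP count set at their bound, the median was -6.06. Gm4340 fell from 220 ± 46.2 CPM to no count, at least 2300-fold lower, and Gm4027 from 157 ± 21.4 to 0.317 ± 0.0241 CPM. The list passed the camera test (adjusted p = 2.32e-68), also with an estimated correlation (adjusted p = 0.0151). Most members belong to multi-copy families whose copies may share reads. Such members are not independent, which the preset correlation of 0.01 does not allow for. The 7 members counted outside such families had a median of -1.24, with 4 lower and 1 higher. Early zygotic transcripts of the major activation wave did not pass as a list by camera (adjusted p = 0.717), but fry called them lower (adjusted p = 0.0137). Of 35 members 5 were higher and 11 lower (6 and 11 adjusted over the list alone). Without control replicate 1 these were 10 and 11. Nop58, Ncl and Hspa8 rose by 1.98 ± 0.24, 1.41 ± 0.22 and 1.22 ± 0.22 on the log2 scale, while Nhp2 fell by 1.51 ± 0.32.

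Camera tests with the preset correlation of 0.01 called 18 of 32 tested lists, 13 higher and 5 lower. With an estimated correlation 2 calls held, the 2-cell-transient genes and ribosome biogenesis. Fry called 19 lists. It lost mitochondrially encoded proteins, histone-modifying enzymes, chromatin remodellers, ribosomal proteins and the proteasome (fry adjusted p = 0.0786, 0.298, 0.0534, 0.187 and 0.122). Added as lower were early zygotic, apoptosis, glycolysis, later-stage marker and sperm lists (fry adjusted p = 0.0137, 0.00782, 0.0369, 0.0223 and 0.0064). Cholesterol genes were added as higher (fry adjusted p = 0.0223). Camera sets a list against all other genes, so its direction was up, without a call, for p53 targets, DNA methylation genes and the tricarboxylic acid cycle, whose medians were -0.06 and whose means were -0.23, -0.19 and -0.06, and for xenobiotic genes, whose median was 0.08 and mean -0.43. With library size alone the calls of DNA damage response, histone-modifying enzymes, RNA polymerase II, proteasome and cumulus markers were lost (adjusted p = 0.0506, 0.0843, 0.0611, 0.0556 and 0.0566), and with at least 10 CPM in 3 libraries 8 calls were lost, among them ribosomal proteins, translation factors and DNA replication (adjusted p = 0.0627, 0.113 and 0.132).

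Of 69 tested maternal oocyte transcripts, RNA stored in the egg, 41 were higher and 2 lower (45 and 3 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 3.72e-14; adjusted p = 0.256 with an estimated correlation). Padi6, a component of the egg's cytoplasmic lattices, was at 380 ± 49.2 CPM in control and 2183 ± 412 CPM in EtP. Nlrp9b was at 641 ± 72.4 and 2558 ± 255 CPM. These values compare polyadenylated RNA between groups at a single stage and do not show a change over time. With library size alone, 16 members were higher and 8 lower, and without EtP replicate 1 the counts were 27 and 1. Genes of maternal mRNA clearance gave 11 higher and 2 lower of 32 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000523, adjusted p = 0.282 with an estimated correlation). Btg4, Cpeb1, Pabpn1l, Ybx2 and Zfp36l2 are in both this and the maternal oocyte list, so the results of these lists are not separate. The decapping factor Dcp1a rose from 331 ± 52.2 to 2572 ± 361 CPM, the poly(A)-binding Pabpn1l by 2.94 ± 0.25, the cytoplasmic polyadenylation factor Cpeb1 by 2.29 ± 0.23 and the deadenylase subunit Cnot3 by 1.60 ± 0.23 on the log2 scale. The majority of the clearance list turned with library size alone, to 4 higher and 12 lower.

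Of 61 ribosome biogenesis genes 30 were higher and 6 lower (34 and 7 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 5.21e-11; adjusted p = 0.0151 with an estimated correlation). Ddx18 and Rrp1b rose by 2.58 ± 0.23 and 2.03 ± 0.21. With library size alone the median was -0.01, with 19 higher and 12 lower. Of 78 cytosolic ribosomal protein genes 34 were lower and 7 higher (38 and 7 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 0.00832; adjusted p = 0.743 with an estimated correlation). Rpl3 fell by 2.58 ± 0.30, while Rpl4 and Rpl13 rose by 2.75 ± 0.23 and 2.69 ± 0.25. Without control replicate 1 the median was -0.35, 12 genes were higher and 26 lower and the list was not called (camera adjusted p = 0.439), and 21 genes were lower without EtP replicate 1 or EtP replicate 3.

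Translation factors gave 13 higher and 3 lower of 48 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00656, adjusted p = 0.161 with an estimated correlation), among them Eif3c, Eif2b4, Eif3e and Eif2s2, which rose by 1.95, 1.82, 2.08 and 2.03. The proteasome gave 11 higher and 3 lower of 38 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0148, adjusted p = 0.604 with an estimated correlation). Psmd12 and Psmd1 rose by 2.24 and 1.85 and Psmb2 fell by 2.37, and the list call was lost without control replicate 3 (adjusted p = 0.0625). RNA polymerase II and elongation factors gave 13 higher and 2 lower of 48 (15 and 2 adjusted over the list alone; camera adjusted p = 0.0148, adjusted p = 0.202 with an estimated correlation), with Gtf2f2, Polr2b, Cdk7 and Mnat1 higher by 2.00, 1.59, 1.82 and 1.77. The spliceosome did not pass (camera adjusted p = 0.474), with 12 higher and 13 lower of 56 (12 and 14 adjusted over the list alone). In the main scaling its members went both ways, Prpf3 rising by 2.03 and Snrpc falling by 2.11, and its mean was -0.11 where its median was 0.03. The majority turned to decreases with library size alone for translation factors (4 higher and 16 lower), the proteasome (5 and 15) and RNA polymerase II (6 and 22), and the spliceosome gave 4 and 30. Single libraries moved these counts too. Translation factors gave 6 higher and 1 lower without EtP replicate 1 and 7 and 1 without control replicate 2, RNA polymerase II 8 and 2 without EtP replicate 1 and 20 and 5 without control replicate 1, and the proteasome 17 and 5 without control replicate 1. Spliceosome genes gave 7 higher and 6 lower without EtP replicate 1 and 7 and 10 without control replicate 2.

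**Figure D3:**
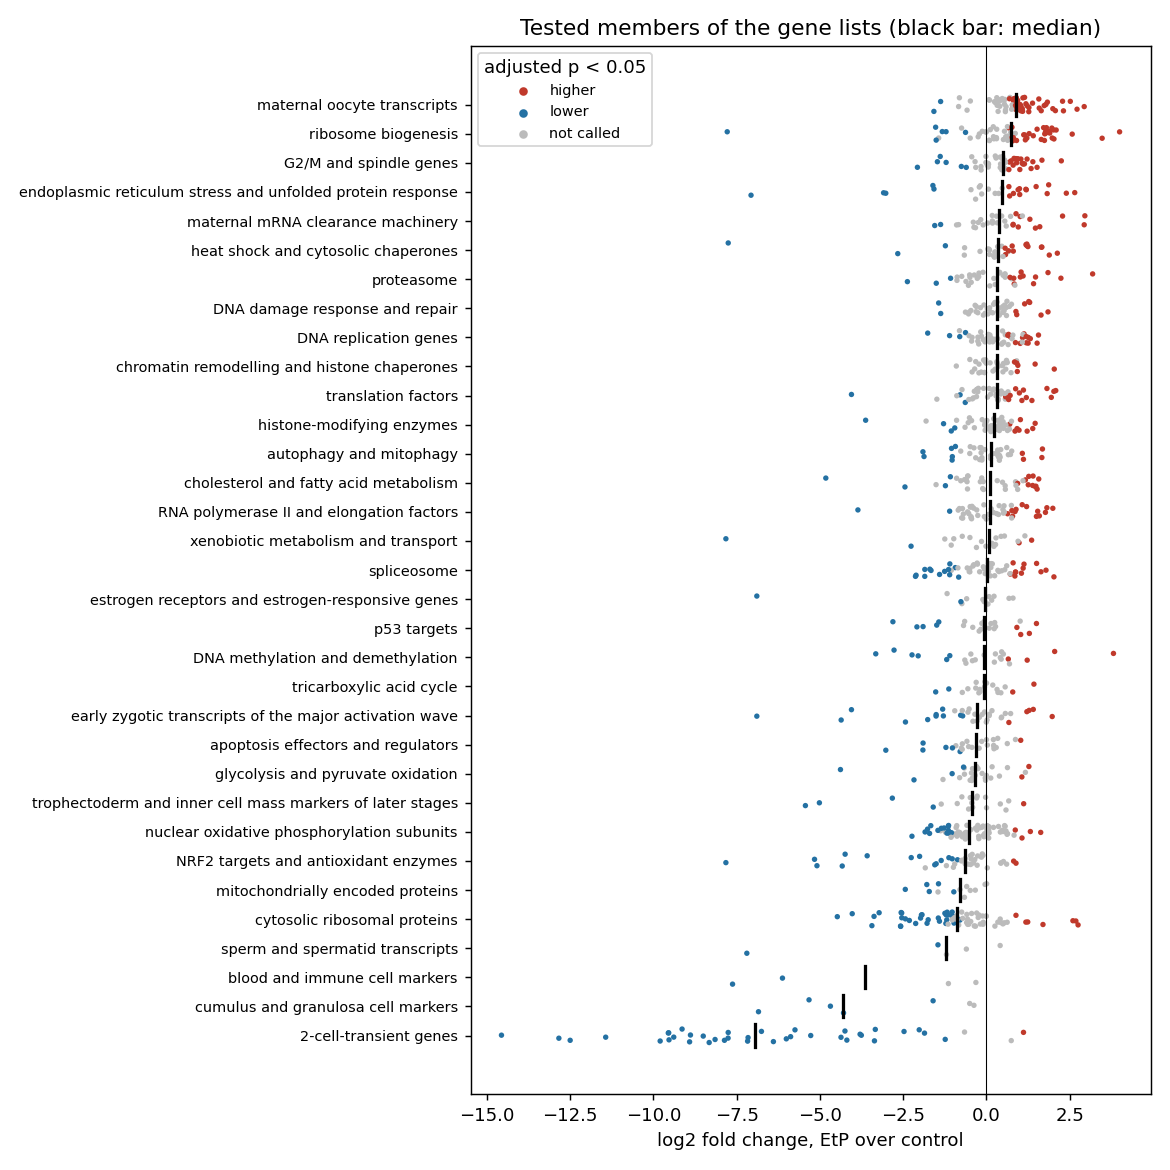
Each point is a tested member of one of 33 gene lists, placed by its fitted log2 fold change of EtP over control and coloured by its call, and black bars are list medians. The 2-cell-transient genes lie lowest with a median of -6.96 and the maternal oocyte transcripts highest with a median of 0.88. Folds of genes without EtP counts depend on the prior count, and with library size alone medians lie lower.

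Genes of cell division were higher more often than lower in the main scaling, and lower more often with library size alone, which gave 5 higher and 16 lower for G2/M, 2 and 14 for DNA replication and 3 and 12 for DNA damage genes. For G2/M and spindle genes 20 of 50 were higher and 6 lower (21 and 6 adjusted over the list alone; camera adjusted p = 0.000435, adjusted p = 0.204 with an estimated correlation). Kif23, a kinesin of the central spindle, rose from 377 ± 5.99 to 1796 ± 203 CPM, and Prc1, Kif4 and Top2a by 1.67, 1.34 and 1.40 on the log2 scale. DNA replication genes gave 14 higher and 4 lower of 50 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00474, adjusted p = 0.204 with an estimated correlation), including Orc1, Rfc1, Orc5 and Cdc6, higher by 1.57, 1.52, 1.25 and 1.20. DNA damage response and repair gave 7 higher and 2 lower of 43 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00749, adjusted p = 0.282 with an estimated correlation). The checkpoint kinase Chek1 rose from 853 ± 189 to 2061 ± 184 CPM, and Parp2, Nbn and Xrcc6 by 1.85, 1.64 and 1.30. Without EtP replicate 1 the counts were 12 higher and 3 lower for G2/M and 6 and 1 for replication genes, and without control replicate 2 they were 13 and 4, and 9 and 2. Replication genes also gave 9 and 2 without EtP replicate 2. DNA damage genes gave 15 and 4 without control replicate 1, 13 and 2 with RLE and 15 and 2 with DESeq2. Targets of p53 did not pass (camera adjusted p = 0.697), with 4 higher and 5 lower of 23 (4 and 5 adjusted over the list alone). The lower ones numbered 2 without control replicate 2, EtP replicate 1 or EtP replicate 2, and 3 without control replicate 3. With library size alone p53 targets gave 2 higher and 13 lower. Mdm4, an inhibitor of p53, rose by 1.29 and Plk2 fell by 2.81. Apoptosis genes did not pass (camera adjusted p = 0.591), with 1 higher and 6 lower of 26 (2 and 10 adjusted over the list alone). Without control replicate 2 there were 2 lower, and 3 without EtP replicate 1 or EtP replicate 3. The higher one in the main fit was Bcl2l10, an egg-expressed member of the BCL2 family, at 3073 ± 485 CPM in control and 6288 ± 483 in EtP.

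Of 42 NRF2 targets and antioxidant enzymes 14 were lower and 2 higher (17 and 2 adjusted over the list alone; camera adjusted p = 0.00321, adjusted p = 0.21 with an estimated correlation). The ferritin chain Ftl1 fell from 74.3 ± 5.54 to 26.1 ± 0.17 CPM and Glrx5 by 1.36 ± 0.25. Prdx6 and Fth1 fell, with log2 fold changes of -1.12 and -1.02, and both calls were lost when some single libraries were left out. Of 13 mitochondrially encoded proteins 5 were lower and 0 higher by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.695 with an estimated correlation). Members moved unequally, mt-Cytb falling by 1.79 ± 0.30 and mt-Nd5 by 1.71 ± 0.24 while mt-Nd1 was at 0.01 ± 0.31, and the list call was lost without control replicate 1 (adjusted p = 0.138) or EtP replicate 3 (adjusted p = 0.0579). Nuclear oxidative phosphorylation subunits did not pass (camera adjusted p = 0.507), with 4 higher and 14 lower of 75 (3 and 12 adjusted over the list alone), nor did glycolysis (adjusted p = 0.657; 2 higher and 4 lower of 29, the same adjusted over the list alone), the tricarboxylic acid cycle (adjusted p = 0.591; 2 and 2 of 19, 2 and 1 adjusted over the list alone) or autophagy (adjusted p = 0.287; 4 and 6 of 38, the same adjusted over the list alone). Without control replicate 3 the nuclear subunits passed (adjusted p = 0.0443; 7 higher and 29 lower), without control replicate 1 there were 10 higher and 11 lower with a median of -0.10, and without EtP replicates 1, 2 and 3 there were 4, 7 and 5 lower. Glycolysis gave 8 lower without control replicate 1 and 2 without each of the other libraries, and autophagy 3 lower without EtP replicate 1 or 3. Ldhb, a lactate dehydrogenase subunit, rose from 1869 ± 287 to 4534 ± 233 CPM, Atg5 rose by 1.67 ± 0.19 and Fundc1 fell by 1.87 ± 0.25.

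Chaperone genes were higher more often than lower in the main scaling, but with library size alone heat shock genes gave 4 higher and 7 lower and endoplasmic reticulum stress genes 5 and 7. Heat shock and cytosolic chaperones gave 13 higher and 3 lower of 33 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00251, adjusted p = 0.161 with an estimated correlation), with Hsp90aa1 rising from 688 ± 224 to 2551 ± 359 CPM and Dnaja1 by 2.13 ± 0.30. The higher ones numbered 8 without EtP replicate 1 or EtP replicate 3. Endoplasmic reticulum stress genes gave 13 higher and 5 lower of 27 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00519, adjusted p = 0.21 with an estimated correlation). Dnajc3, Pdia3 and Creld2 rose by 2.65, 2.40 and 1.87, and Dnajb9 fell by 3.09. Cholesterol and fatty acid genes did not pass (camera adjusted p = 0.0973), with 10 higher and 4 lower of 36 (14 and 8 adjusted over the list alone), the higher ones including Fdft1, Hmgcs1 and Hadha, and 3 higher and 18 lower with library size alone. Without control replicate 1 these numbered 14 and 8. Estrogen receptors and responsive genes, included because parabens bind estrogen receptors weakly, did not pass (adjusted p = 0.905; 0 higher and 2 lower of 14 by edgeR, the same adjusted over the list alone), nor did xenobiotic metabolism and transport (adjusted p = 0.657; 2 and 2 of 20, the same adjusted over the list alone). Tiparp, a target of the aryl hydrocarbon receptor, rose by 0.98 ± 0.22.

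DNA methylation genes did not pass as a list (camera adjusted p = 0.403), with 4 higher and 6 lower of 23 (4 and 6 adjusted over the list alone). With at least 10 CPM in 3 libraries the list was called higher (camera adjusted p = 0.0468). Beside Dnmt1, the imprint regulator Zfp57 rose from 3667 ± 573 to 15200 ± 1493 CPM and Dppa3 by 1.23 ± 0.26, while Dnmt3l fell by 1.19 ± 0.24. Histone-modifying enzymes gave 8 higher and 4 lower of 51 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0451, adjusted p = 0.695 with an estimated correlation), and this call was lost without control replicate 1, EtP replicate 2 or EtP replicate 3 (adjusted p = 0.411, 0.07 and 0.0608). The higher ones numbered 4 without control replicate 2, EtP replicate 1 or EtP replicate 2. Ezh2 and Setdb1 rose by 1.47 and 1.23. Chromatin remodellers and histone chaperones gave 6 higher and 0 lower of 36 by edgeR (5 and 0 adjusted over the list alone; camera adjusted p = 0.0148, adjusted p = 0.282 with an estimated correlation), with Hmgb1 and Hmgb2 higher by 1.47 and 2.04. Histone-modifying enzymes gave 1 higher and 15 lower with library size alone, and chromatin remodellers 2 and 11. Chromatin remodellers that were higher numbered 3 without control replicate 2 or EtP replicate 1 and 10 without control replicate 3.

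Of 7 tested cumulus and granulosa markers 5 were lower (the same adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.282 with an estimated correlation), each at a few CPM or less in control. Without control replicate 2 there were 3 lower. Gja1 fell from 3.24 ± 1.14 to 0.147 ± 0.169 CPM, while Cyp19a1 was at 22.1 ± 11.7 and 17.1 ± 1.42 CPM. Sperm transcripts did not pass (adjusted p = 0.339; 0 higher and 2 lower of 5, the same adjusted over the list alone), with Odf2 at 86.1 ± 40.5 CPM in control and 115 ± 14.05 in EtP. Prm2 fell from 7.43 ± 3.16 to 2.71 ± 0.244 CPM, a call lost without EtP replicate 1 (edgeR adjusted p = 0.06). Of 4 blood and immune markers, too few for camera, 2 were lower (3 adjusted over the list alone). Markers of later trophectoderm and inner cell mass did not pass (adjusted p = 0.507; 1 higher and 4 lower of 19, 2 and 5 adjusted over the list alone), with Dab2 at 121 ± 2.58 and 182 ± 31.5 CPM and Dppa1 at 40.4 ± 17.1 and 40.6 ± 3.14 CPM in control and EtP.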

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

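Directions of the called named genes did not flip under any alternative run. The only reversal with a call was for Dppa1, uncalled in the main fit, which was at -0.70 with library size alone (edgeR adjusted p = 0.048); this goes with the shift of the median of all genes by -0.73 under that scaling. Ncoa3, Abcc4, Abcc1, Dab2 and Odf2, uncalled in both, also turned negative there, as did the medians of 12 called lists. The removals of ribosomal RNA rows and of rows without an Ensembl ID were chosen after seeing the data. Genes higher in EtP numbered 1797 in the main fit, 545 with library size alone, 978 with at least 10 CPM in 3 libraries and 918 at adjusted p below 0.01; genes lower numbered 2601, 7618, 1453 and 1404 under the same settings. The stricter filter tests fewer genes and moved fold changes by -0.25, the counts at adjusted p below 0.01 follow from the stricter threshold, and those with library size alone go with the shift of -0.73. Leaving out each library gave 1097 to 2637 genes higher and 1661 to 2890 lower. Without EtP replicate 1 the counts were 1097 and 1661, and 1730 and 1733 genes were lower without EtP replicate 2 and EtP replicate 3, with fewer samples in each fit. RLE gave 52.4% and upper-quartile scaling 64.7% of calls as decreases. The 140 named genes include some that were uncalled in the main fit and had no call to lose. Of the called ones 12 lost their call when at least 1 library was left out. With library size alone 20 lost it, and 7 uncalled genes gained one in the same direction. Lists called numbered 18 in the main test, 10 with at least 10 CPM in 3 libraries, 2 with an estimated correlation and 15 to 18 without single libraries. Fry called 19, of which 6 were new, and lost 5 of the 18. The cause of the change with an estimated correlation was not tested. The difference in genes detected was -6512 at 1 count, -3400 at 10 counts and -3104 at 1 CPM, with an exact permutation p of 0.1 each. Whether equal replicate numbers pair the libraries cannot be told from 3 libraries per group. Deviations of equal numbers correlated at 0.127, 0.003 and 0.273, and those of unequal numbers at -0.228 to 0.111. Not every library correlated best with its own number. With the replicate block 2296 genes were higher, 3024 lower and 18 lists called. Pseudocount and filter alternatives for normalized units did not apply to counts. Depth limits mainly genes of a few counts.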

Other observations

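Families defined by shared symbol stems and chromosomes were tested after the data were seen, by Fisher's exact test with adjustment over both directions, families against all tested genes and chromosomes against protein-coding ones. Of 366 families, Ddx RNA helicases (16 higher and 1 lower of 35, adjusted p = 0.000477), Fbxw F-box genes (13 and 2 of 23, adjusted p = 0.000433), Nlrp genes (8 and 0 of 12, adjusted p = 0.00334), Tcl genes (6 and 0 of 6, adjusted p = 0.000925) and Orc origin-recognition genes (5 and 0 of 6, adjusted p = 0.0199) held more increases than other genes, and Rpl (5 higher and 21 lower of 50, adjusted p = 0.0171) and Tdpoz genes (0 and 5 of 5, adjusted p = 0.0202) more decreases. Rpl genes gave 17 lower with RLE and 36 with library size alone, and the list of all cytosolic ribosomal proteins was not called without control replicate 1 (camera adjusted p = 0.439). With library size alone the counts of the first group became 6 and 5, 10 and 5, 4 and 2, 1 and 0, and 1 and 1. Of 408 protein-coding genes on the X chromosome, 108 were lower and 22 higher (adjusted p = 5.25e-07 for decreases and 6.67e-05 for increases over 20 chromosomes), with 280 lower and 8 higher with library size alone. Chromosome 14 held more increases (70 of 408, adjusted p = 0.0332) and chromosome 7 more decreases (172 of 898, adjusted p = 0.0332); with library size alone both held more decreases than increases (203 and 23, 520 and 32). Genes of a family or chromosome are not independent replicates.

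The tests below were chosen after the results were seen, except those of thinning and of ribosomal protein genes, whose bounds were set before their values were computed. For the loss of 2-cell-transient genes, reads shared between near-identical copies are argued against by family sums, which conserve such reads. The Zscan4 sum fell from 334 ± 26.7 to 24.5 ± 2.17 CPM (SD, n = 3), a log2 ratio of -3.77, and the ratios of the Usp17l and Tdpoz sums were -6.57 and -6.99. Scaling is argued against because the list median lay between -6.87 and -7.46 over 4 scalings, which moved the median of all genes by up to 0.73. Of the 7 members counted outside multi-copy families, 4 were called lower and 3, Zfp352, Kdm4dl and Spz1, at least 8-fold lower. Families were assigned by gene symbol, and copy number was not tested. The loss thus reached some genes outside the families so defined, which need not be single-copy. Random genes matched on abundance gave a mean of 0.26 at that fold, and the largest p over 4 scalings and 6 left-out libraries was 0.0016. Counting every called decrease, p was 0.0039, and 0.128 with library size alone. The fold limit was set with the members' values known, after a first bound on quartiles had left a loss limited to families open. The p at that fold therefore cannot decide whether members outside families fell more often than other genes. The loss was not shared by all 7, whose median was -1.24 with a range of -8.50 to 1.12 (-2.82 had Duxf3 and Obox genes been counted outside, a grouping revised after values were seen). An earlier time of EtP embryos within the stage and changed transcription may both give this loss together with maternal transcripts at 0.88. The design cannot separate them, and the labels do not give the hour of collection of either group.

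Detection of more genes in control is not explained by library size, since the difference was -6450 genes after thinning every library to the smallest total, against a largest range of 948 within a group. Nor is it explained by a few genes taking most of the counts, since thinning counts outside the 50 most abundant genes left -6078. In all, 1836 annotated genes had reads in every control library and none in EtP, against 29 in reverse. Genomic DNA in control libraries could account for part: reads at the density of gene families taken as silent would give 20.1% of the 1836. That density was 0.201 to 0.235 CPM per kb in control and 0.122 to 0.177 in EtP libraries (library totals without TMM). Such reads were thus not confined to control. Among tested genes were 62 Olfr and 28 Vmn receptor genes, so such families need not be silent here. Their transcripts would make the 20.1% too high. The share neither excludes genomic DNA nor accounts for the whole. Thinning equalizes counts but not the number of embryos per library, which the labels do not give. Low-level transcription in control embryos also remains open and was not tested.

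Lower ribosomal protein genes could reflect the weaker signal of short genes. No random list matched on exon length and abundance lay as low. The median of -0.88 was at the percentile 0.01, the smallest 10000 lists can give, against a random median of -0.29. Exon length joined all annotated exons of a gene and can exceed the length of its mRNA, so an effect of short mRNA was not excluded. Without control replicate 1 the median was -0.35 at percentile 0.29. Counts summed with named pseudogenes gave a median log2 ratio of -0.89 over 63 genes, so that reads moved to them do not account for it; pseudogenes without such names were not included. EtP exposure and embryo stage remain open and were not tested apart.

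For the number of genes changed, 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 1797 genes higher and 2601 lower and the highest other split 0 by edgeR (32 to 815 genes at unadjusted p below 0.05, and 0 by limma-voom); in each case 1 split, the real one, reached the real count. For gene lists the real split gave 18 and the highest other 15. Every other split keeps part of the group difference, so these counts do not measure false calls.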
